A study of Mus musculus with 8 samples.

How the data were processed

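RNA sequencing was done on hand-picked pancreatic islets of C57BL/6J mice given a high-fat diet with 60 kcal% fat for 2 weeks, starting at 10 weeks of age. The samples fell into 2 groups by the genotype in the labels, 5 samples with an intact insulin-degrading enzyme gene (Ide+/+) and 3 samples without it (Ide-/-). The labels call the samples biological replicates and do not say how many animals each islet sample came from. If some shared an animal, the p-values would measure only the spread between these samples.

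Per the labels' protocols, RNA was purified with a column kit, 100 ng of RNA with an integrity number above 6.5 entered each library, and libraries were made with a low-input kit from NEB. Reads were aligned with STAR 2.7.1a and counted with RSEM 1.3.1 on the mouse build GRCm38, per the submitters' processing notes. The gene annotation release and the strand setting were not given in the sources used here. The deposited files hold 1 table per sample, with an expected count and a TPM value for each of 55487 Ensembl gene identifiers. An expected count is the RSEM estimate of the reads from a gene, with reads that match several genes divided among them by a model, and the authors deposited it without normalization. TPM, as deposited by the authors, is corrected for transcript length and sums to the same total in each sample, so it is a share of the library.

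Gene symbols and positions were taken from GENCODE M21 on GRCm38, which held 55227 of the identifiers. No symbol was found for 260 identifiers, and 229 identifiers shared a symbol with another. The expected counts were rounded to whole numbers. The main comparison was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust dispersion, TMM library scaling, the default low-count filter (a minimum count of 10 scaled to library size and a total of 15) and genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are Ide-/- over Ide+/+, with a standard error (SE) computed as the fold change divided by the square root of F. CPM values are edgeR's counts relative to library size with TMM scaling, and group values are means ± SD with n = 5 for Ide+/+ and n = 3 for Ide-/-. The steps were tested on simulated counts with these group sizes, with 200 genes changed 2-fold or 4-fold and a further gene list changed by less. The low-count filter then left 14980 genes. Of the changed genes that passed it, 20.9% of the 2-fold changes and 80.0% of the 4-fold changes were called. Of 98 calls 3 were unchanged genes, and 0 had the wrong sign. The simulated groups otherwise had the same gene proportions. The simulation therefore did not cover the shift in composition of the real libraries, whose TMM factors ran from 0.41 to 2.06.

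In all, 22 gene lists and 9 cell type marker lists were fixed before the data were examined. They covered beta, alpha, and delta and PP cell markers, immature beta cells, ER chaperones, the ATF4 stress response, cell cycle, the Reg family, proteasome, autophagy, interferon, oxidative stress, heat shock, fatty acid oxidation, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, the mitochondrial genome, secretory granules, insulin and IGF signalling, prolactin receptor and serotonin, immediate early genes, and neighbours of Ide. The marker lists covered acinar, duct, endothelial, fibroblast and stellate, macrophage, lymphocyte, Schwann, fat and red blood cells. The symbol Ero1b, in the beta cell list, had no matched identifier and was left out, and for Ddit3 and Atp5o the identifier with more counts was used. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. All list p-values were adjusted by the Benjamini-Hochberg method over the lists tested. The acinar share of counts was tested with a two-sided exact permutation test over all 56 splits of the samples into 5 and 3, whose smallest possible p is 0.0179. The other marker lists were tested in the same way, and over the 9 lists fewer than 4 together could not pass an adjusted p of 0.05. The same exact test was run on the mean log2 CPM of each list, a test added after the data were seen. Genes within 10 Mb of Ide were compared with all other tested genes by a two-sided Fisher's exact test of called against not called, Ide left out.

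The genes to name were chosen by a rule written before the values were seen. It took Ide, then the 12 called genes with the largest rise and the 12 with the largest fall among annotated genes with a mean of at least 1 CPM and with every Ide-/- library on the same side of the Ide+/+ mean. It added up to 4 called members of each list by smallest p, or otherwise the 2 members with the highest mean CPM. Pik3ap1 and Cela2a were named after their values were seen. The values of 2 genes that the rule names are not reported here, so the named genes are not the full set that the rule gives, though the counts of their lists include them. Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Reg2, Mki67, Hspa5, Ddit3, Nnt, Hhex and Kif11 were always named.

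Library totals ranged from 7143415 to 33371642 counts. The widest 95% Wilson interval was ± 0.022 percentage points for an acinar share of a library, ± 0.033 for a mitochondrial share and ± 0.012 for a Malat1 share. These intervals and the floor of 3 counts used for genes without counts cover counting error only, since reads are not independent molecules. Genes in families of near-identical sequence (the amylase genes Amy2a1 to Amy2a5, trypsinogens such as Prss1 and Prss3, Serpina1a and Serpina1b, the Reg genes, histone and globin genes, Ins1 and Ins2, and the pseudogene Tmem181c-ps) share reads that RSEM divides, so the values of single members are uncertain.

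The alternatives set beforehand were median-ratio (RLE) size factors, DESeq2 1.42.0, limma-voom with quality weights, limma on log2(TPM + 1), no low-count filter, a filter of at least 1 CPM in 3 libraries, the replicate block, the log2 acinar share as a covariate, removal of acinar and mitochondrial genes, each library left out in turn, other thresholds, and windows of 5 and 20 Mb around Ide. Added after the data were seen were library scaling to the secretory granule list, Ide+/+ replicates 2 and 3 summed as 1 library, Ide+/+ replicate 1 and Ide-/- replicate 3 both left out, an acinar list with Amy2a1 to Amy2a4 added, the comparison of the cell cycle list with random lists matched on transcript length and mean expression, and the sum of the overlapping Nnt gene models. The secretory granule scaling sets values relative to endocrine RNA. Ide+/+ replicates 2 and 3 were far closer to each other than any other pair, with r = 0.990 across genes in log2 CPM and a median chi-square of 1.92 times that of sampling noise, against 5.63 to 405 times for the other pairs. They still differed by more than sampling noise and were kept as 2 samples, though this does not show that they came from different animals. The exact permutation tests take them as 2 independent samples. With the 2 summed as 1 library, 1359 genes were higher and 1637 lower in Ide-/- islets.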

Results

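Transcript levels were measured by RNA sequencing in hand-picked islets from mice that ate a high-fat diet for 2 weeks. The comparison asked how the loss of insulin-degrading enzyme (IDE), a metalloprotease that cleaves insulin and other short peptides, alters islet gene expression under this metabolic stress. The 5 Ide+/+ libraries (replicates 1 to 5) held 24620301, 33371642, 24479078, 26513150 and 19277269 counts. The 3 Ide-/- libraries were shallower, with 17445935, 13237930 and 7143415 counts.

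Ide (ENSMUSG00000056999; GRCm38 chromosome 19, 37268743 to 37337852, minus strand) was close to absent in every library labelled Ide-/-. Its level was 39.2, 19.5, 20.3, 28.3 and 27.5 CPM in the Ide+/+ libraries and 0.167, 0.285 and 0.367 CPM in the Ide-/- libraries, where it rested on 6, 7 and 4 counts. The log2 fold change was −6.74 (SE 0.39, adjusted p = 6.2e-06, edgeR quasi-likelihood test). The labels give all animals as female, but the counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were 0 only in Ide+/+ replicate 1. In the other 7 libraries Ddx3y had 503 to 2139 counts. Xist, the transcript of the inactive X chromosome, had 692 counts in Ide+/+ replicate 1 and at most 11 in any other library. By these counts Ide+/+ replicate 1 was female and the other 7 libraries male, against the labels. The Ide+/+ group thus held both sexes, and sex was not a term in the comparison. The deposited file of Ide+/+ replicate 1 also carries another prefix number than the other 7 files.

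Transcripts of acinar cells, the exocrine cells that surround islets and secrete digestive enzymes, were far lower in Ide-/- libraries. All 30 acinar markers fell in Ide-/- islets (30 also when adjusted over the list alone), with a median log2 fold change of −6.32. The markers took 36.6% ± 9.31 of counts in Ide+/+ libraries (SD, n = 5) and 1.41% ± 0.53 in Ide-/- libraries (SD, n = 3, exact permutation p = 0.0179, the smallest possible, and 0.080 adjusted over the 9 marker lists). Per library the share was 45.6%, 26.3%, 26.7%, 42.2% and 42.2% in Ide+/+ and 0.80%, 1.65% and 1.79% in Ide-/-. With the amylase genes Amy2a1 to Amy2a4 added, the share was 40.9% to 76.4% in Ide+/+ and 1.09% to 2.63% in Ide-/-. Ctrc (chymotrypsin C) fell from 229 ± 129 to 2.91 ± 1.59 CPM, Pnliprp2, a pancreatic lipase-related protein, from 1929 ± 1191 to 21.8 ± 10.4 CPM, and the kallikrein Klk1 from 1764 ± 943 to 29.5 ± 13.4 CPM. Ptf1a, the transcription factor of acinar identity, fell from 17.4 ± 13.4 to 0.077 ± 0.11 CPM. The adjusted p of the set test was 1.4e-31 at the preset correlation, and adjusted p = 0.286 with an estimated correlation. Shares of other RNA in the unscaled totals, which include the acinar counts, differed between the genotypes too. Mitochondrial transcripts took 0.470% of counts in Ide+/+ replicate 1, 4.38% to 8.17% in the other 4 Ide+/+ libraries and 8.87%, 13.96% and 27.1% in Ide-/- libraries. The nuclear RNA Malat1 took 0.1003% to 1.21% in Ide+/+ and 2.13% to 5.65% in Ide-/-. Fewer acinar counts in the total raise both shares. How much of the Malat1 rise (group means 0.733% and 4.28%) this accounts for was not tested, and no TMM-scaled value of Malat1 is given here. With TMM scaling the mean log2 CPM of the mitochondrial genes was 10.9 ± 1.34 in Ide+/+ and 11.2 ± 0.88 in Ide-/- (exact permutation p = 0.839).

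**Figure D1:**
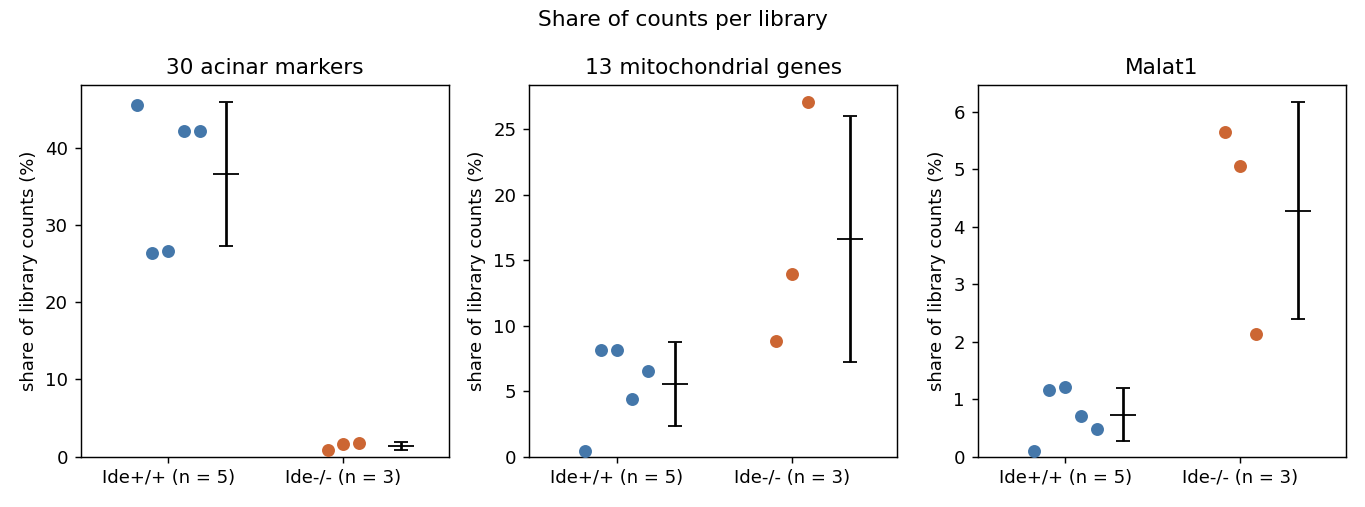
Share of all counts in each library taken by 30 acinar markers, 13 mitochondrial genes and Malat1 (y axes, percent of library counts), with points for libraries and black bars for group means ± SD. The Ide-/- libraries lie at 0.80% to 1.79% for acinar markers, against 26.3% to 45.6% in Ide+/+ libraries.

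Of 16266 tested genes, 1699 were higher and 1727 lower in Ide-/- islets, so that 49.6% of the called genes were higher. At least 2-fold changes numbered 1077 upward and 1241 downward. The balance of directions differed between settings. With libraries scaled to secretory granule genes 608 genes were higher and 1362 lower (30.9% higher), and the median of all genes moved from −0.01 to −0.13 on the log2 scale. On log2(TPM + 1) values tested with limma, 5987 were higher and 412 lower (93.6% higher), with a median of all genes at +0.50, a setting that changes the test, the unit and the scaling together. The counts fell by more than 1.5 times without Ide+/+ replicate 4 (993 higher, 1101 lower) and without Ide-/- replicate 1 (864 and 971), 2 (785 and 809) or 3 (694 and 853). With the acinar share as a covariate edgeR called 0 genes (1155 at an unadjusted p under 0.05, and no other tool was run with this term), and Ide itself was not called (adjusted p = 0.69). The median SE was then 5.39 times as large, since the acinar shares of the genotypes did not overlap.

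Genes of the cell cycle rose in Ide-/- islets. Of 39 tested members 27 were higher and 0 lower (28 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.53. Mki67 (ENSMUSG00000031004; chromosome 7, 135689784 to 135716361), the gene of the proliferation antigen Ki-67, rose from 3.68 ± 2.07 to 20.01 ± 3.26 CPM (log2 fold change 2.36, SE 0.37, adjusted p = 0.0017). Its 3 Ide-/- values lay between 17.5 and 23.7 CPM and its 5 Ide+/+ values between 1.40 and 5.88 CPM. The kinetochore gene Cenpf rose from 3.76 ± 1.35 to 21.3 ± 6.597 CPM, and Cdc20, an activator of the anaphase-promoting complex, from 2.03 ± 0.28 to 7.42 ± 1.75 CPM. The mitotic cyclin gene Ccnb1 rose from 2.21 ± 0.56 to 8.31 ± 0.62 CPM and the spindle gene Nusap1 from 1.84 ± 0.30 to 5.31 ± 0.56 CPM. With secretory granule scaling 22 members were higher and the median was 1.43. In that scaling 10000 random lists matched on transcript length and mean expression, a comparison added after the data were seen, had a median of −0.11, and the cell cycle median lay above all of them. The random lists were drawn gene by gene and not as genes that vary together, so they do not measure the spread between libraries. The mean log2 CPM of the list was 1.56 ± 0.31 in Ide+/+ and 2.84 ± 0.21 in Ide-/- (exact permutation p = 0.0179, the smallest possible, and 0.060 adjusted over the 30 lists). The set test gave an adjusted p of 4.1e-12 at the preset correlation, and adjusted p = 0.287 with an estimated correlation. The rise went with an acinar share of 36.6% in Ide+/+ and 1.41% in Ide-/-. Mki67 was 1.40, 5.88, 5.47, 3.95 and 1.72 CPM in Ide+/+ replicates 1 to 5, whose acinar shares were 45.6%, 26.3%, 26.7%, 42.2% and 42.2%.

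Macrophage markers fell together. Of 16 tested members 13 were lower and 0 higher (14 lower when adjusted over the list alone), with a median log2 fold change of −1.87. The MHC class II genes H2-Eb1 and H2-Aa, which present antigen on macrophages and other immune cells, fell from 33.6 ± 5.49 to 7.94 ± 1.78 CPM and from 40.04 ± 8.89 to 10.6 ± 3.43 CPM. H2-Eb1 had a log2 fold change of −2.10 (SE 0.23, adjusted p = 0.00045). The macrophage surface receptor genes Cx3cr1 and Adgre1, the latter encoding F4/80, fell from 2.57 ± 1.03 to 0.181 ± 0.097 CPM and from 3.38 ± 1.10 to 0.445 ± 0.14 CPM. The set test gave an adjusted p of 1.1e-10, and adjusted p = 0.286 with an estimated correlation. As a share of all unscaled counts the markers took 0.0403% ± 0.019 in Ide+/+ and 0.0246% ± 0.0038 in Ide-/-, a difference within the spread between libraries (exact permutation p = 0.268). Their mean log2 CPM was 3.21 ± 0.38 in Ide+/+ and 1.47 ± 0.26 in Ide-/- (exact permutation p = 0.0179, the smallest possible, and 0.060 adjusted over the 30 lists). The lower count was 7 on log2(TPM + 1) values. The acinar share moved with this group as with the cell cycle genes.

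Other cell types of the islet surroundings did not move as one. Duct markers fell, with 9 of 12 lower (10 when adjusted over the list alone), a median of −1.81 and a set test adjusted p of 1.2e-06, but adjusted p = 0.089 with an estimated correlation. The count was 5 without Ide-/- replicate 2 and 4 without Ide-/- replicate 3. The mucin gene Muc1 fell from 35.0 ± 22.0 to 0.771 ± 0.037 CPM and the keratin gene Krt19 from 17.5 ± 8.37 to 1.62 ± 0.20 CPM. The trefoil factor gene Tff2 fell from 898 ± 455 to 22.6 ± 10.4 CPM and the keratin gene Krt8 from 133 ± 33.7 to 39.4 ± 7.22 CPM, beside the fall of the acinar share. None of 12 endothelial markers was called with edgeR, adjusted over all genes or over the list alone (1 at an unadjusted p under 0.05), although limma-voom called 1 higher and 1 lower and limma on log2(TPM + 1) called 4 higher. The VEGF receptor genes Kdr and Flt1 had 52.9 ± 19.9 and 51.4 ± 24.7 CPM in Ide+/+ and 48.3 ± 11.7 and 66.4 ± 26.5 CPM in Ide-/-. The endothelial median was 0.02 and the mean −0.08, while the set test pointed upward (adjusted p = 0.73). Of 13 fibroblast and stellate markers 1 was lower (also 1 when adjusted over the list alone), Acta2, the smooth muscle actin gene, at −0.74 (SE 0.17, adjusted p = 0.011), a call lost without Ide-/- replicate 1 or 2 and of the other sign on log2(TPM + 1) values (0.12). The set test adjusted p was 0.73, and without Ide+/+ replicate 1 the lower count was 2. Of 5 tested lymphocyte markers 3 were lower (3 when adjusted over the list alone), among them the immunoglobulin genes Ighm (−2.46) and Igkc (−4.48) and the B cell receptor gene Cd79a (−1.99), with a set test adjusted p of 0.178. The lymphocyte count was 1 without any 1 of the Ide-/- libraries, and Igkc and Cd79a were then not called, nor was Cd79a without Ide+/+ replicate 4. Of 3 tested Schwann cell markers 1 was higher (1 when adjusted over the list alone), with a set test adjusted p of 0.29, and the count was 0 without Ide+/+ replicate 2, 3 or 4 or Ide-/- replicate 2 or 3 and 2 without Ide-/- replicate 1. The only tested fat cell marker, Fabp4, had 17.0 ± 5.24 and 26.3 ± 6.03 CPM (log2 fold change 0.62, adjusted p = 0.11). Its unadjusted p was under 0.05, which over a list of 1 tested gene is also the p of the list alone. None of 5 red blood cell genes was called by edgeR, adjusted over all genes or over the list alone (0 at an unadjusted p under 0.05), or by DESeq2 or limma-voom, and the set test adjusted p was 0.68. The globin genes Hba-a2 and Hbb-bs had log2 fold changes of −0.12 (adjusted p = 0.88) and −0.31 (adjusted p = 0.60), and on log2(TPM + 1) values Hba-a2 was called higher (1.02).

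**Figure D2:**
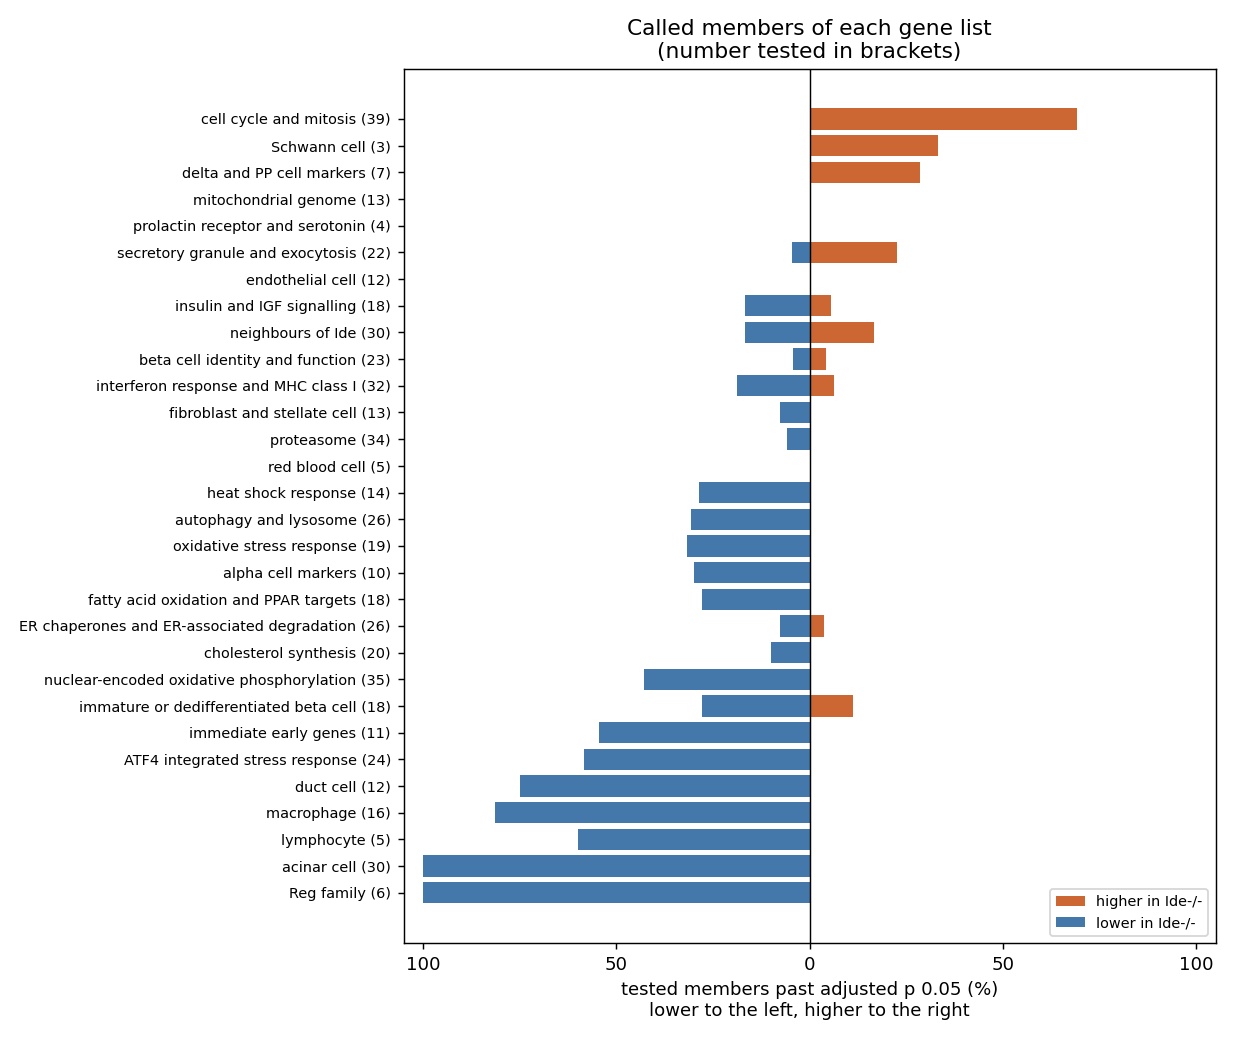
Percent of the tested members of each gene list past an adjusted p of 0.05, with members lower in Ide-/- islets drawn to the left and members higher to the right (x axis, percent), and the number tested after each name (y axis, ordered by median log2 fold change). The cell cycle list has 27 of 39 members higher, and the acinar list has 30 of 30 lower.

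Genes of the Reg family, secreted lectins that acinar cells express strongly and islets induce on injury, fell with the acinar markers. All 6 tested members were lower (6 when adjusted over the list alone), with a median of −7.13 against −6.32 for the acinar list. Reg1 (ENSMUSG00000059654; chromosome 6, 78422711 to 78428667) fell from 14278 ± 9170 to 208 ± 117 CPM and Reg2 from 638 ± 717 to 4.57 ± 4.54 CPM. Reg3b and Reg3d fell from 140 ± 151 to 1.16 ± 0.85 CPM and from 114 ± 72.4 to 1.61 ± 1.08 CPM. The set test gave an adjusted p of 3.5e-06, and adjusted p = 0.287 with an estimated correlation. Without the low-count filter 2 of the 6 were called, and with limma-voom 3.

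Many targets of ATF4, the transcription factor of the integrated stress response, were lower in Ide-/- islets. Of 24 ATF4 list members 14 were lower and 0 higher (15 lower when adjusted over the list alone), with a median of −1.43. The serine synthesis genes Phgdh and Psat1 fell from 74.5 ± 33.7 to 4.66 ± 1.65 CPM and from 20.8 ± 8.70 to 3.32 ± 0.43 CPM. Phgdh (ENSMUSG00000053398; chromosome 3, 98313170 to 98339990) had a log2 fold change of −3.97 (SE 0.45, adjusted p = 0.00050). Slc7a11, the cystine transporter gene, fell from 3.04 ± 2.13 to 0.149 ± 0.096 CPM, and Eif4ebp1, a translation repressor gene, from 41.0 ± 18.4 to 7.26 ± 0.83 CPM. The set test gave an adjusted p of 7.4e-07, and adjusted p = 0.287 with an estimated correlation. The mean log2 CPM of the list was 3.89 ± 0.46 in Ide+/+ and 2.38 ± 0.02 in Ide-/- (exact permutation p = 0.0179, and 0.060 adjusted). On log2(TPM + 1) values 7 members were lower and 2 higher. Phgdh was 39.2 to 40.2 CPM in Ide+/+ replicates 2 and 3, whose acinar shares were near 26%, and 80.2 to 111 CPM in the other 3 Ide+/+ libraries, whose shares were 42.2% to 45.6%. Ddit3, the gene of the ER stress factor CHOP, had 10.6 ± 1.26 and 11.4 ± 2.73 CPM and was not called (adjusted p = 0.75).

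Of 26 ER chaperone and degradation genes 1 was higher and 2 lower (1 and 1 when adjusted over the list alone), with a median of −0.63 and a set test adjusted p of 0.0043, but adjusted p = 0.665 with an estimated correlation. Sel1l, a scaffold of ER-associated degradation, fell from 348 ± 147 to 85.3 ± 3.93 CPM. The cochaperone gene Dnajc3 had 398 ± 180 and 164 ± 54.0 CPM (adjusted p = 0.048), a call lost without any 1 of Ide+/+ replicates 1, 4 and 5 and the Ide-/- libraries. The chaperone gene Hyou1 rose from 13.6 ± 4.94 to 28.7 ± 6.97 CPM, a call lost without Ide-/- replicate 1 or 3. The lower count was 5 without Ide+/+ replicate 2 or 3 and 1 without any 1 of the other 6 libraries. Hspa5, the gene of the main ER chaperone BiP, had 1304 ± 627 and 679 ± 173 CPM and was not called (adjusted p = 0.14). Of 14 heat shock genes 4 were lower (5 when adjusted over the list alone), with a set test adjusted p of 0.0055, but adjusted p = 0.415 with an estimated correlation. Hspb1 fell from 12.1 ± 1.02 to 4.76 ± 0.45 CPM and Hspa1a from 9.89 ± 8.003 to 1.37 ± 0.21 CPM, and the other 2 were Cryab (−1.81) and Hspd1 (−0.93). Without any 1 of the Ide-/- libraries 2 heat shock genes were lower, and Hspa1a was not called without replicate 3, Cryab without replicate 1 or 2, and Hspd1 without any 1 of them or Ide+/+ replicate 4. Of 19 oxidative stress genes 6 were lower (8 when adjusted over the list alone), with a set test adjusted p of 0.0026, but adjusted p = 0.415 with an estimated correlation. They included Nfe2l2, the gene of the antioxidant regulator NRF2 (log2 fold change −1.02), the metallothionein genes Mt1 (−2.74) and Mt2 (−2.87) and the peroxidase gene Gpx4 (−1.03). The count was 3 without Ide-/- replicate 3, where Gpx4 was not called. Of 11 tested immediate early genes 6 were lower (7 when adjusted over the list alone), with a set test adjusted p of 2.7e-04, but adjusted p = 0.089 with an estimated correlation. Junb and Jun fell from 6.14 ± 1.84 to 1.02 ± 0.42 CPM and from 29.4 ± 9.87 to 6.76 ± 2.43 CPM, and Ier2 and Btg2 had log2 fold changes of −1.52 and −1.17. The count was 3 without Ide-/- replicate 2, and Btg2 was not called without replicate 2 or 3. The acinar share fell alongside each of these lists.

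Of 26 autophagy and lysosome genes 8 were lower (9 when adjusted over the list alone), with a median of −0.58 and a set test adjusted p of 3.7e-04, but adjusted p = 0.415 with an estimated correlation. The lysosomal protease gene Ctsd fell from 98.5 ± 30.004 to 35.7 ± 6.46 CPM, and Map1lc3a, which encodes an LC3 protein of the autophagosome, from 21.5 ± 3.83 to 10.4 ± 1.06 CPM. The cathepsin genes Ctsb and Ctsl fell from 180 ± 55.7 to 63.6 ± 12.4 CPM and from 92.2 ± 30.9 to 33.2 ± 4.57 CPM. Without any 1 of the Ide-/- libraries 5 were lower. Of 34 proteasome genes 2 were lower (2 when adjusted over the list alone), Psmb5 at −1.03 and Psmb7 at −0.93, with a set test adjusted p of 0.034, but adjusted p = 0.840 with an estimated correlation. Psmb7 was not called without any 1 of the Ide-/- libraries, leaving 1 proteasome gene, and the lower count was 4 without Ide+/+ replicate 1 or 2. Of 32 tested interferon and MHC class I genes 2 were higher and 6 lower (3 and 8 when adjusted over the list alone), with a set test adjusted p of 0.18. The lower ones included Psmb10, an immunoproteasome subunit gene (−2.68), and Tap2, a peptide transporter gene (−1.03), whose call was lost without Ide-/- replicate 2 or 3. The MHC class I gene H2-D1 was at −0.95 and the RNA sensor gene Ifih1 at −0.73, calls lost without Ide-/- replicate 2 or 3 and without replicate 1 or 2. The lower count was 3, 1 and 2 without Ide-/- replicate 1, 2 and 3, and the higher count was then 0. On log2(TPM + 1) values the proteasome list had 13 members higher and 0 lower, and the autophagy list had 4 higher and 0 lower. The median of all genes in that setting was +0.50. The acinar share (36.6% in Ide+/+ and 1.41% in Ide-/-) moved with these lists, as did the macrophage markers, of which 13 of 16 were lower.

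Some members of several metabolic lists were lower relative to the TMM scale. Of 35 nuclear-encoded oxidative phosphorylation genes 15 were lower (19 when adjusted over the list alone), with a median of −0.79 and a set test adjusted p of 3.2e-06, but adjusted p = 0.586 with an estimated correlation. Cox4i1, a cytochrome oxidase subunit gene, fell from 120 ± 22.3 to 60.2 ± 2.65 CPM and Cyc1, the cytochrome c1 gene, from 39.1 ± 7.93 to 19.7 ± 3.28 CPM. On log2(TPM + 1) values 8 members were higher and 0 lower, but the median of all genes was then +0.50, above Cox4i1 at 0.022. With TMM scaling the lower count was 3, 0 and 0 without Ide-/- replicate 1, 2 and 3. Cox5a and Atp5b, subunit genes of cytochrome oxidase and ATP synthase, had log2 fold changes of −1.38 and −1.11, and on log2(TPM + 1) values Atp5b was at 0.41. Cox4i1 was not called without any 1 of the Ide-/- libraries, nor Cyc1, Cox5a or Atp5b without replicate 2 or 3. Of 18 fatty acid oxidation and PPAR target genes 5 were lower (10 when adjusted over the list alone), with a set test adjusted p of 8.3e-04, but adjusted p = 0.394 with an estimated correlation. The peroxisomal enzyme gene Ehhadh fell from 2.93 ± 1.02 to 0.508 ± 0.15 CPM, and Pdk4, a kinase gene that restrains pyruvate oxidation, from 12.7 ± 2.22 to 5.69 ± 0.92 CPM. Acot1, a thioesterase gene, was at −1.81, a call lost without any 1 of the Ide-/- libraries, where 3 were lower. Of 20 cholesterol synthesis genes 2 were lower (0 when adjusted over the list alone), Stard4 at −0.84 (adjusted p = 0.036), a sterol carrier gene, and Fdps at −0.78 (adjusted p = 0.044), with a set test adjusted p of 0.0069, but adjusted p = 0.665 with an estimated correlation. Both calls were lost without any 1 of the Ide-/- libraries or without Ide+/+ replicate 4, and that of Fdps also without Ide+/+ replicate 5. The count was 6 without Ide+/+ replicate 1, 4 without replicate 2 and 1 without replicate 5. On log2(TPM + 1) values both genes had positive fold changes (0.0091 and 0.065), below the median of all genes in that setting (+0.50). None of 13 genes of the mitochondrial genome was called by edgeR, adjusted over all genes or over the list alone (1 at an unadjusted p under 0.05), and the set test adjusted p was 0.68. DESeq2 called 0, limma-voom 1 lower, and edgeR without Ide+/+ replicate 1 also 1 lower. The log2 fold changes of mt-Co1 and mt-Cytb were 0.26 (SE 0.72, adjusted p = 0.82) and 0.74 (SE 0.79, adjusted p = 0.53). The acinar share moved with all of these lists.

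Most endocrine identity genes were not called. Of 23 matched beta cell genes 1 was higher and 1 lower (1 and 1 when adjusted over the list alone). The median was −0.12 and the mean −0.18, while the set test pointed upward (adjusted p = 0.93). Rfx6, a transcription factor gene of islet development, rose from 38.4 ± 4.76 to 74.1 ± 5.09 CPM (log2 fold change 0.95, SE 0.19, adjusted p = 0.0053). With secretory granule scaling it was not called (0.79, adjusted p = 0.086). The cation channel gene Trpm5 fell from 23.9 ± 21.8 to 4.51 ± 1.52 CPM, a call lost without Ide-/- replicate 1 or 3, and without Ide+/+ replicate 1 there were 3 higher. The insulin genes Ins1 and Ins2 had 12299 ± 5946 and 55627 ± 26585 CPM in Ide+/+ and 16601 ± 1994 and 69305 ± 8266 CPM in Ide-/-, and were not called (adjusted p = 0.62 and 0.76). Iapp, the amylin gene, had 7034 ± 4710 and 5844 ± 1768 CPM (adjusted p = 0.77). On log2(TPM + 1) values, which are shares of the library, Ins1 and Ins2 were called higher (1.48 and 1.32) and 9 beta cell genes were higher. Of 10 alpha cell markers 3 were lower (4 when adjusted over the list alone), with a set test adjusted p of 0.0061, but adjusted p = 0.415 with an estimated correlation. They included the amino acid transporter gene Slc38a5 (from 123 ± 65.0 to 11.6 ± 4.25 CPM) and the somatostatin receptor gene Sstr2 (from 3.87 ± 0.68 to 0.933 ± 0.28 CPM). The transcription factor gene Irx1 was at −1.42 (adjusted p = 0.046), a call lost without any 1 library other than Ide+/+ replicate 1. Slc38a5 is also expressed in acinar cells. The count was 6 without Ide+/+ replicate 1. Gcg, the glucagon gene, had 48256 ± 9537 and 37105 ± 13129 CPM and was not called (adjusted p = 0.69). Of 7 delta and PP cell markers 2 were higher (2 when adjusted over the list alone), with a set test adjusted p of 0.24. Sst, the somatostatin gene, had 1817 ± 517 and 4650 ± 2024 CPM (log2 fold change 1.36, adjusted p = 0.047). The Sst call was lost without any 1 library other than Ide+/+ replicate 1, with secretory granule scaling (adjusted p = 0.11) and with RLE size factors (adjusted p = 0.050). Sstr3, a somatostatin receptor gene, rose from 14.8 ± 3.99 to 32.3 ± 10.3 CPM, a call lost without Ide-/- replicate 3. Ppy, the pancreatic polypeptide gene, had 5862 ± 2503 and 8839 ± 4459 CPM (adjusted p = 0.46).

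Of 18 tested genes of immature or dedifferentiated beta cells 2 were higher and 5 lower (3 and 9 when adjusted over the list alone), with a set test adjusted p of 0.043, but adjusted p = 0.415 with an estimated correlation. Sox9, also a duct cell transcription factor gene, fell from 12.7 ± 3.07 to 2.54 ± 0.77 CPM, and the lactate dehydrogenase gene Ldha from 23.5 ± 5.42 to 8.42 ± 1.21 CPM. The catalase gene Cat fell from 16.6 ± 5.47 to 5.21 ± 1.17 CPM, while Aldh1a3, a retinaldehyde dehydrogenase gene used as a marker of dedifferentiated beta cells, rose from 0.415 ± 0.22 to 2.61 ± 1.43 CPM (log2 fold change 2.51, SE 0.45, adjusted p = 0.0033). The lower count was 8 without Ide+/+ replicate 1 and 3 without Ide-/- replicate 1 or 3. The acinar share (36.6% in Ide+/+ and 1.41% in Ide-/-) and the macrophage markers (13 of 16 lower) moved with genotype too. The falls of Sox9, Ldha and Cat therefore cannot be assigned to beta cells. Of 22 secretory granule and exocytosis genes 5 were higher and 1 lower (6 and 1 when adjusted over the list alone), with a set test adjusted p of 0.32. The SNARE gene Snap25 rose from 77.5 ± 9.33 to 144 ± 10.1 CPM and the calcium sensor gene Syt7 from 20.3 ± 4.74 to 36.9 ± 2.33 CPM. Pam, a peptide-amidating enzyme gene, had a log2 fold change of 0.79, and the SNARE gene Stx1a, the lower member, of −1.11. The Pam call was lost with scaling to this list and without Ide+/+ replicate 4 or any 1 of the Ide-/- libraries, and the Stx1a call without Ide+/+ replicate 2, 3 or 4 or any 1 of the Ide-/- libraries. The Snap25 and Syt7 calls were lost with scaling to this list itself and without Ide-/- replicate 2, Snap25 also without replicate 1 and Syt7 without replicate 3. The higher count was 2 without Ide+/+ replicate 4, 3 without Ide+/+ replicate 5, and 1, 0 and 1 without Ide-/- replicates 1, 2 and 3. Of 18 insulin and IGF signalling genes 1 was higher and 3 lower (1 and 4 when adjusted over the list alone), with a set test adjusted p of 0.68. Igf1, a growth factor gene, fell from 32.9 ± 21.7 to 1.81 ± 0.37 CPM, beside the fall of the acinar share. Its log2 fold change was −3.82 without Ide+/+ replicate 1 (acinar share 45.6%) and −4.41 without Ide+/+ replicate 2 (26.3%). The cell type that expressed it was not resolved. The kinase gene Akt1 and the regulatory subunit gene Pik3r1 were at −0.68 and −0.58, calls lost with secretory granule scaling and without Ide+/+ replicate 4 or any 1 of the Ide-/- libraries, and of the other sign on log2(TPM + 1) values (0.27 and 0.35). Pik3ca, a kinase subunit gene, rose from 13.5 ± 1.37 to 22.3 ± 5.56 CPM, a call lost without Ide+/+ replicate 4 or Ide-/- replicate 3 and with secretory granule scaling. The lower count was 1 without Ide+/+ replicate 4 and without any 1 of the Ide-/- libraries. None of 4 tested genes of the prolactin receptor and serotonin list was called by edgeR, adjusted over all genes or over the list alone (0 at an unadjusted p under 0.05), with a set test adjusted p of 0.68, while limma-voom called 3 higher. Prlr had 179 ± 160 and 254 ± 32.5 CPM (adjusted p = 0.52), and without Ide+/+ replicate 1 it was called higher (1.21, adjusted p = 0.0099). Socs2 had 14.7 ± 11.6 and 14.8 ± 0.42 CPM (adjusted p = 0.98), and was called without the same library (0.61, adjusted p = 0.020).

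The exact permutation test of mean log2 CPM gave no list an adjusted p under 0.05, and fewer than 11 of the 30 lists together could not have passed. The smallest possible p of 0.0179 (0.060 adjusted) was reached by 9 lists, the acinar, duct, macrophage, cell cycle, ATF4, Reg, immediate early, autophagy, and immature beta cell lists. The exact permutation p was 0.036 (0.067 adjusted) for the alpha cell, oxidative stress, heat shock, fatty acid oxidation, oxidative phosphorylation, lymphocyte and Schwann lists. For lists past the set test at the preset correlation it was higher in 3, at 0.089 for cholesterol synthesis (0.158 adjusted), 0.125 for ER chaperones (0.208) and 0.196 for the proteasome (0.295). For the others the exact permutation p was 0.179 for delta and PP cells, 0.214 for insulin and IGF signalling, 0.393 for secretory granules, 0.464 for interferon, 0.554 for neighbours of Ide, 0.714 for prolactin receptor and serotonin, 0.732 for beta cells, 0.839 for the mitochondrial genome, 0.911 for red blood cells, 0.982 for endothelial cells and 1 for fibroblast and stellate cells. With secretory granule scaling the smallest possible p was also reached by 9 lists, with heat shock and lymphocytes in place of autophagy (exact permutation p = 0.036) and immature beta cells (p = 0.125).

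**Figure D3:**
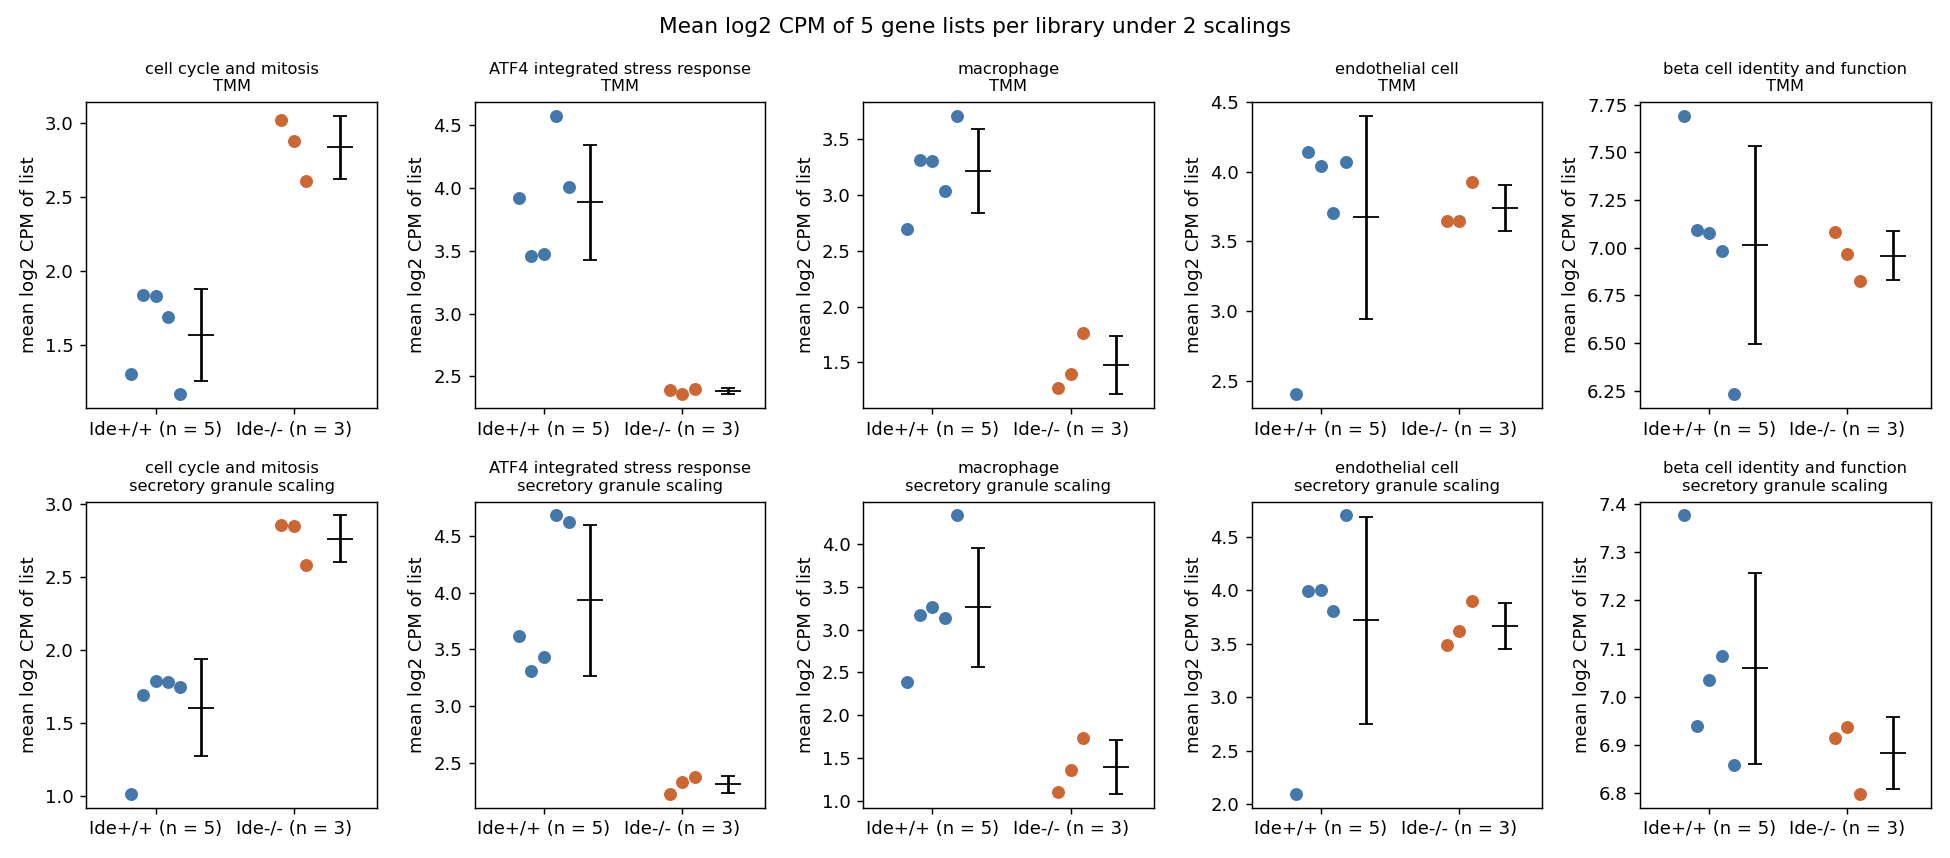
Mean log2 CPM of 5 gene lists in each library (y axes), with TMM scaling in the upper row and secretory granule scaling in the lower row, points for libraries and black bars for group means ± SD. The cell cycle list lies at 2.61 to 3.03 in Ide-/- and 1.16 to 1.84 in Ide+/+ libraries with TMM scaling.

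The 12 largest rises among annotated genes were led by Mc5r, a melanocortin receptor gene, from 0.199 ± 0.21 to 6.29 ± 2.85 CPM (log2 fold change 4.64, SE 0.55, adjusted p = 5.6e-04). The others were Crhbp, which encodes a binding protein of corticotropin-releasing hormone (3.53), Fyb2 (3.51), the protease inhibitor genes Serpina1b and Serpina1a (both 3.43), Tmem181c-ps (3.27), the kinesin gene Kif2c (2.98), Gsto2 (2.96), Cngb3 (2.95), Pyroxd2 (2.91), the histone gene Hist1h2br (2.86) and the mitotic gene Depdc1a (2.81). Serpina1a was 6.77 CPM in Ide-/- replicate 1 and 0.569 and 1.10 CPM in the other 2, and without replicate 1 neither Serpina1a nor Serpina1b was called. Hist1h2br was not called without Ide+/+ replicate 4 or any 1 of the Ide-/- libraries. Among the 12 largest falls, Cela3a, Nxph2 and Cytl1 had 0 counts in all 3 Ide-/- libraries. Against a floor of 3 counts over the group they were at least 154-fold, 68.9-fold and 55.99-fold lower than in Ide+/+ islets. The bounds were 76.7-fold, 34.2-fold and 27.8-fold without Ide-/- replicate 1 and 101-fold, 45.2-fold and 36.7-fold without Ide-/- replicate 2, and that of Nxph2 was 41.4-fold without Ide+/+ replicate 1. The trypsinogen gene Prss1 had 1 count in the Ide-/- libraries together, for a ratio of 406 with a 95% counting interval of 73.0 to 16055. The ratio was 202 without Ide-/- replicate 1, and without replicate 2, which held the count, Prss1 was at least 88.8-fold lower. Amy2a1, a pancreatic amylase gene, fell from 128360 ± 104570 to 600 ± 400 CPM and Gp2, a zymogen granule membrane gene, from 6127 ± 5066 to 37.5 ± 24.4 CPM. Log2 fold changes were −8.38 for Reg3a, −7.63 for Tmed11, −7.57 for Ptf1a, −7.55 for Reg3g, −7.50 for Prss3 and −7.27 for Serpini2.

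Genes near Ide were compared with the rest of the genome, since sequence around a targeted locus can differ from that of the control strain. Within 10 Mb on either side (chromosome 19, 27268743 to 47337852) 46 of 177 tested genes were called (26.0%), against 3376 of 16077 elsewhere (21.0%). The odds ratio was 1.32 (95% interval 0.92 to 1.87, two-sided Fisher's exact p = 0.11). By the same exact test it was 1.74 within 5 Mb (p = 0.033), 1.19 within 20 Mb (p = 0.24) and 1.88 without Ide-/- replicate 3 (p = 0.0032), and on log2(TPM + 1) values it was 0.79 (p = 0.14). Of the 100 genes with the smallest p, Ide left out, 2 lay in the window, against 1.09 expected from its share of tested genes. The gene there with the smallest p, named after its value was seen, was Pik3ap1, a signalling adaptor gene, which fell from 13.045 ± 2.75 to 0.852 ± 0.21 CPM (log2 fold change −3.99, SE 0.29, adjusted p = 4.4e-05). Pyroxd2 (chromosome 19, 42725858 to 42752775) rose from 2.25 ± 0.90 to 17.7 ± 3.28 CPM. Of 30 tested genes in the fixed list of neighbours 5 were higher and 5 lower (5 and 6 when adjusted over the list alone), with a set test adjusted p of 0.68. The lower count was 8 without Ide+/+ replicate 1 and 3 and 2 without Ide-/- replicates 1 and 2, and the higher count was 3 without Ide+/+ replicate 2, 3 or 4 or Ide-/- replicate 2 or 3. Hells and Kif20b, which act in dividing cells, rose from 1.83 ± 0.37 to 5.02 ± 0.39 CPM and from 2.85 ± 1.06 to 13.1 ± 6.08 CPM, as did the cytokinesis gene Cep55 (2.16), while the glycogen regulator gene Ppp1r3c fell (−1.53). Kif11, a spindle kinesin gene beside Ide, and Hhex had log2 fold changes of 0.86 (adjusted p = 0.11) and −0.86 (adjusted p = 0.16). Hhex was called without Ide+/+ replicate 1 (−1.05, adjusted p = 0.034).

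Nnt, which carries a deletion in C57BL/6J but not in C57BL/6N mice, is annotated as 2 overlapping gene models on chromosome 13. ENSMUSG00000025453 rose from 3.98 ± 1.67 to 15.9 ± 4.36 CPM (log2 fold change 1.96, adjusted p = 0.0022). ENSMUSG00000116207 had 13.6 ± 6.22 and 6.89 ± 3.11 CPM (−0.94, adjusted p = 0.10), and was called lower without Ide+/+ replicate 2 (−1.11, adjusted p = 0.043). Their sum, computed after the data were seen, was 17.6 ± 6.00 CPM in Ide+/+ (n = 5) and 22.8 ± 3.11 CPM in Ide-/- (n = 3), a difference within the spread between libraries (exact permutation p = 0.179).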

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

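The comparison of each library with its group was set beforehand, and no test in this part was chosen after the results were seen. In 20 of 139 measures 1 of the 5 Ide+/+ libraries lay far from the other 4, by a gap of over 0.71 of the range of the group. Chance flags about 1 in 20 groups, and the measures of a library are not independent of each other. The Ide-/- group, with 3 libraries, was not tested.

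Of the 20 measures 15 were in Ide+/+ replicate 1, the library without Y-linked counts and with another prefix number on its file. Whether it came from another cohort is not given in the sources used here. Xist was at 28.1 CPM in it, against 0.0754 to 0.449 CPM in the other Ide+/+ libraries. Higher than in the others were Iapp at 15188 CPM (3065 to 6305), Prlr at 460 CPM (58.6 to 145), Socs2 at 35.4 CPM (8.07 to 11.3) and Trpm5 at 62.3 CPM (8.26 to 17.2). The same was true of Muc1 at 73.5 CPM (19.6 to 30.9), Nxph2 at 7.52 CPM (0.916 to 2.68), Igkc at 8.42 CPM (0.215 to 2.56) and Psmb7 at 45.5 CPM (22.6 to 28.97). The sterol genes Stard4 and Fdps were at 15.5 CPM (8.02 to 8.37) and 48.1 CPM (23.8 to 30.04), Hspd1 at 152 CPM (74.7 to 82.3) and Cd79a at 5.41 CPM (1.07 to 1.35). Lower than in the others were Kdr at 18.5 CPM (54.2 to 67.1) and Kif20b at 1.002 CPM (3.004 to 3.65).

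In Ide+/+ replicate 4 Jun was at 46.7 CPM (22.6 to 27.3 in the other 4) and Slc7a11 at 6.71 CPM (1.71 to 3.11). In Ide+/+ replicate 5 Sox9 was at 18.03 CPM (10.54 to 12.5), and the globin genes Hbb-bs and Hba-a2 were at 366 CPM (115 to 158) and 498 CPM (120 to 166). No explanation of these values was tested.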

How the results depend on the processing

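Secretory granule scaling, the summed libraries and the pair of libraries left out together were chosen after the data were seen. Ide stayed lower and past the threshold in every alternative except the acinar covariate, between −6.91 and −6.39 with 1 library left out. Of 129 other named log2 fold changes, 110 were called, and 75 of these calls held with each library left out in turn. Over the values of these genes in all alternatives, 2164 kept direction and side of the threshold, 276 lost the call, 20 gained one and 108 changed sign. Where no cause is given below, the cause was not tested. The Ide-/- depths of 7143415 to 17445935 counts limit genes with few counts most.

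Called genes numbered 694 to 2141 higher and 809 to 2139 lower with 1 library left out, 511 and 678 at an adjusted p under 0.01, 3363 and 3351 with limma-voom, and 5987 and 412 with limma on log2(TPM + 1). With secretory granule scaling 608 were higher. Whether the replicate numbers pair animals is not given in the sources used here. Deviations of same-numbered libraries from their group means had r of 0.049, 0.0092 and −0.093. Other pairs had r of −0.30 to 0.24, so these values showed no pairing but cannot exclude it. With the replicate numbers as a block 465 were higher and 706 lower. With an estimated correlation 0 lists passed the set test, against 17 at the preset one. With fry 15 passed. The fry adjusted p was 0.0033 for cell cycle, 0.0025 for macrophage, 0.0071 for ATF4 and 0.00015 for immediate early genes. It was 0.083 for oxidative phosphorylation, 0.23 for ER chaperones and for cholesterol synthesis, and 0.37 for the proteasome, lists that had passed at the preset correlation. The odds ratio near Ide was 1.16 to 1.88 with 1 library left out, 1.74 within 5 Mb, 1.19 within 20 Mb and 0.789 on log2(TPM + 1). It had no value with the acinar covariate, where no gene was called.

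The signs of some log2 fold changes turned. With DESeq2 Socs2 was −0.011. With limma-voom Ppy was −0.0019, Hbb-bs 0.19, Iapp 0.060, mt-Co1 −0.040 and Hba-a2 0.46. With limma on log2(TPM + 1) Acta2 was 0.12, Cox4i1 0.022, Psmb7 0.0015, Stard4 0.0091, Fdps 0.065, Hbb-bs 0.75, Gcg 0.48, Iapp 0.80, Kdr 0.71, Atp5b 0.41, Akt1 0.27, Pik3r1 0.35 and Hba-a2 1.02. The median of all genes in that setting was +0.50, and of these only Hbb-bs, Iapp, Kdr and Hba-a2 lay above it. The turned signs of the others are therefore not rises relative to other genes. With the block Hbb-bs was 0.25, Kdr 0.11, Hba-a2 0.62 and Socs2 −0.13. With secretory granule scaling Ddit3 was −0.044, mt-Co1 −0.016 and Socs2 −0.0011. With Ide+/+ replicates 2 and 3 summed Socs2 was −0.073. Without Ide+/+ replicate 1 and Ide-/- replicate 3 Ppy was −0.10, mt-Cytb −0.37, Flt1 −0.27, Iapp 0.38 and mt-Co1 −0.62. With 1 library left out Iapp was −0.54 to 0.22, mt-Co1 −0.33 to 0.58, mt-Cytb −0.095 to 1.197, Socs2 −0.14 to 0.61, Hbb-bs −0.44 to 0.14, Hba-a2 −0.26 to 0.51, Ddit3 −0.12 to 0.20 and Flt1 −0.0028 to 0.57.

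With the acinar share as a covariate 0 genes were higher and 0 lower, 5 lists passed the set test and Ide was −2.15 (adjusted p = 0.69). The median SE was 5.39 times as large, because the shares of the genotypes did not overlap, so these values do not test stability. The sign turned for 63 genes, with adjusted p of 0.680 or more after rounding. Positive values were Ctrc 2.63, Ptf1a 4.15, Pnliprp2 2.24, Sox9 0.24, Klk1 1.97, Reg3d 4.11, Tmed11 6.29, Serpini2 3.34, Igf1 3.16, Cela3a 2.77, Slc38a5 2.61, Psmb10 1.92, Gp2 5.42, Reg1 3.87, Ldha 0.49, Eif4ebp1 2.16, Amy2a1 4.81, Nxph2 4.59, Nfe2l2 0.072, Reg3b 10.57, Sel1l 0.91, Reg2 10.18, Map1lc3a 0.95, Reg3a 19.12, Reg3g 20.21, Psmb5 0.018, Mt1 4.35, Cox4i1 0.48, Trpm5 1.52, Psmb7 0.19, Stard4 0.59, Fdps 0.86, Hspa5 0.66, Hbb-bs 2.23, Iapp 0.11, Tff2 2.67, Cat 0.999, Ctsl 1.61, Mt2 4.39, Gpx4 0.78, Cox5a 1.57, Cryab 3.69, Acot1 0.87, Ifih1 0.42, Akt1 0.13, Cd79a 2.62, Ier2 0.19, Hspd1 0.20, Dnajc3 0.19 and Hba-a2 3.20. Negative values were Aldh1a3 −2.94, Cenpf −1.24, Cdc20 −0.33, Mki67 −1.79, Kif20b −0.69, Cngb3 −1.42, Rfx6 −0.17, Serpina1a −8.07, Serpina1b −7.72, Snap25 −0.21, Syt7 −0.64, Kif11 −2.05 and Ppy −0.082.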

Other observations

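The tests of carried-over acinar cells, other cell types and preparation were chosen only after the results were seen, as were the secretory granule scaling and the bounds by which the planned acinar share and the planned odds ratio near Ide were read as tests of library scaling and flanking sequence.

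Shares of all unscaled counts were compared for markers of the cell types around the endocrine cells. No adjusted p was under 0.05, which says little, since fewer than 4 of the 9 marker lists together could not have passed and even the acinar share (36.6% and 1.41%) had an adjusted p of 0.080. Schwann cell markers took 0.000646% ± 0.000344 in Ide+/+ (SD, n = 5) and 0.00257% ± 0.000611 in Ide-/- (SD, n = 3, exact permutation p = 0.036, adjusted p = 0.080). Fat cell markers took 0.00135% and 0.00469% (exact permutation p = 0.036, adjusted p = 0.080). Endothelial markers took 0.0254% and 0.0527% (exact permutation p = 0.089, adjusted p = 0.115), fibroblast and stellate markers 0.0330% and 0.0725% (exact permutation p = 0.071, adjusted p = 0.107), and red blood cell markers 0.0346% and 0.0811% (exact permutation p = 0.054, adjusted p = 0.096). Duct markers took 0.124% and 0.0638% (exact permutation p = 0.018, adjusted p = 0.080). Lymphocyte markers took 0.000709% and 0.000554% (exact permutation p = 0.857, adjusted p = 0.857). Acinar markers with the added amylase genes took 58.6% of these totals in Ide+/+ and 2.09% in Ide-/-, which alone raises other shares in Ide-/-. On mean log2 CPM with TMM scaling the Ide-/- minus Ide+/+ difference was 0.067 for endothelial and 0.020 for fibroblast and stellate markers. It was −0.16 for red blood cell and 0.68 for Schwann cell markers. For endothelial, fibroblast and stellate, and red blood cell markers the higher shares therefore do not show more cells. Schwann cell markers, with 3 tested genes, stayed higher on that scale (exact permutation p = 0.036, adjusted p = 0.067). With secretory granule scaling their difference was 0.57 (exact permutation p = 0.232). Fat cell markers, with 1 tested gene, were not compared in this way.

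Acinar transcripts were far lower in every Ide-/- library. Library scaling does not account for this, since the shares of unscaled counts differed by a ratio of group means of 25.9 and did not overlap. A candidate explanation is that fewer acinar cells were carried over with the picked islets, a step meant to leave them out: 83.3% of the 30 tested markers lay within 1 log2 unit of the median fold of −6.32, among them the most abundant, Cela2a (−6.20). The other 5 markers lay outside this band, as did Amy2a1, which is not in the list (−7.74), so the fall was not by 1 common factor for every gene. A change within acinar cells of Ide-/- mice was not tested and stays open.

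Cell cycle genes were higher in Ide-/- libraries. Less dilution of islet RNA by acinar RNA is argued against as the whole cause, since with scaling to secretory granule genes the list median was 1.43 (95% bootstrap interval over members 0.85 to 1.62). More endothelial, fibroblast, macrophage or lymphocyte cells, as read from their markers, are argued against too. Under this scaling the cell cycle median exceeded the highest of these 4 list medians by 1.56 (0.86 to 1.82). Both intervals resample genes, so they do not measure the spread between libraries. Schwann cell markers (median 1.06 with TMM scaling) were not compared. More division within a cell type, without more of its marker RNA, was not tested. Sample preparation that goes with acinar content cannot be told apart from genotype: with the acinar share as a covariate the list median was −0.58, at a median SE 5.39 times as large. More dividing cells in Ide-/- islets may be involved, as a hypothesis only, and the cell type that expressed these genes was not resolved.

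Genes near Ide were called somewhat more often than others, with an odds ratio of 1.32 whose interval (0.92 to 1.87) included 1. Flanking sequence carried with the knockout allele may contribute to single genes such as Pik3ap1, but this comparison cannot assign the change of any single gene to its position. Pik3ap1 fell in the same libraries as the macrophage markers, of which 13 of 16 were lower. The ratio was also not stable, at 1.74 within 5 Mb and 1.88 without Ide-/- replicate 3. No biological explanation was tested.

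Other splits of the 8 libraries into 5 and 3 were compared with the real one. Only the real split, 1 of 56, called as many as 3426 genes, and 1 of 56 is the smallest share this comparison can give. The highest other split called 1189 genes. It set Ide+/+ replicates 2 and 3 (acinar shares 26.3% and 26.7%) and the Ide-/- libraries (0.80% to 1.79%) against Ide+/+ replicates 1, 4 and 5 (42.2% to 45.6%). A division that follows acinar share thus called genes too. Chance is less likely for this number but not excluded, nor is a difference in preparation that follows genotype. As many as the 17 lists past the set test were found in 12 of 56 splits, the highest other having 20, so chance cannot be excluded for the number of lists.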
